A study of Mus musculus with 6 samples.

How the data were processed

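RNA was measured by sequencing in mouse primary mammary luminal cells, the inner epithelial cells of the mammary duct. Per the labels' protocols, the cells were sorted by flow cytometry and grown in DMEM/F12 with 5% FBS, EGF at 10 ng/ml, FGF2 at 20 ng/ml, heparin at 4 µg/ml and the ROCK inhibitor Y-27632 at 5 µM. They were held without serum for 12 hours and then kept for 24 hours in serum-free medium with EFNA3 protein at 0 or 1 µg/ml. The treatment characteristic in the labels put 3 libraries in the control group and 3 in the EFNA3 group. Libraries were made from total RNA with a stranded mRNA kit, per the labels' protocols.

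Per the submitters' processing notes, the authors used Trim Galore, Subread and featureCounts with the mouse build mm39; versions, the annotation and the strand setting are not given in the sources used here. The deposited table held 19739 genes by symbol, with 1 column per library and no unit in its header. Its values ran from -0.79 to 18.1, were not whole and included negative numbers, and were taken as log2 values; the base is inferred, since 2 raised to the value summed to about the size of a read library. The sorted values of the 6 deposited log2 columns differed by at most 0.00302, so the authors' table had been brought to 1 common distribution, as quantile normalization does. The step from reads to log2 values, its prior count and any filter are not given in the sources used here. Library totals and depth are therefore unknown, no counting interval could be given, and a shift of all genes at once could not be seen.

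Columns were assigned to samples by the description label of each sample, and no column was left without a sample. Genes were tested where the value was at least 3.32 (10 on the linear scale) in at least 3 of the 6 libraries, which left 16394. The filter had been set for linear values and was carried to the log2 scale. The comparison was fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values with no pseudocount, a mean-variance trend and no block, as a moderated two-sided test with Benjamini-Hochberg adjustment at 0.05. The labels do not say that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 3 against 3 libraries cannot go below 0.1.

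In all, 44 gene lists for pathways, cell types and RNA quality were fixed with the design before the data were examined, as were the tests, most settings to be varied and the rule for named genes. A list was tested if at least 5 members passed the filter, which held for 43. The main list test was camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it; fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. The rule named the genes with the largest change among those past the threshold with no overlap between groups. Fewer than 5 passed in each direction, so the rule's fallback named the 10 genes per direction with the smallest unadjusted p. Its exceptions were kept: no predicted genes, no overlap between groups, and a mean of at least 5.64 (50 on the linear scale). The rule added every tested ephrin and Eph gene and up to 4 members of each described list, by smallest p; some genes and lists that were tested are not reported here.

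Both steps were tested on simulated data. With 200 of 16394 genes changed in each of 20 draws on the residuals of the deposited values, the limma fit recovered 26.5% of changes of 0.5 on the log2 scale, 67.8% of changes of 1 and 88.5% of changes of 2. These residuals cancel within each group, so estimates were exact and false calls could not arise. With independent noise instead, the fit recovered 28.2%, 64.0% and 88.0%, with 5.45 false calls per draw. In 100 simulated lists of 51 genes, camera with the preset correlation called 8% of lists with no shift and independent noise, and 100% of those shifted by 0.2. It called 61% of lists that had no shift but shared a factor between libraries, against 8% with an estimated correlation.

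Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, replicate blocks and leaving out each library. With the block by the numbers of the descriptions, control replicate 2 and EFNA3 replicate 2 each stood alone in a block. They added nothing to the difference, which came only from replicates 1 and 3 of each group. A correction for transcript length and GC share, and the same with EFNA3 replicate 1 left out, were added after seeing the data. The correction took a spline with 5 degrees of freedom in each property out of every library. Length and GC share were those of the longest annotated transcript of each gene in GENCODE for an earlier mouse build, so no coordinates are given. They were matched by symbol for 97.4% of tested genes. The longest transcript may not be the one expressed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Near-identical gene copies cannot be separated in this table, so values of the serum amyloid genes Saa1 and Saa2, and of ribosomal proteins and their pseudogenes, are uncertain.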

Results

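Gene expression was measured in 6 libraries of cultured primary mouse mammary luminal cells, 3 kept without and 3 with EFNA3 protein at 1 µg/ml for 24 hours. EFNA3 is ephrin-A3, a membrane-anchored ligand of Eph receptors, here added as a protein. All libraries had the same distribution of log2 values, with a median of 8.10, and their depth is unknown. The cultures expressed luminal keratins, with Krt8 at 13.70 ± 0.06 and Krt18 at 13.60 ± 0.09 in controls (log2, SD, n = 3), and the luminal progenitor factor Elf5 at 12.57 ± 0.02. Basal markers ranged widely in level: in controls the basal keratin Krt14 stood at 16.26 ± 0.08 and the contractile gene Tagln at 5.20 ± 0.11, below that median. These genes were chosen for their level and none passed the limma test.

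The comparison asks how EFNA3 protein affects gene expression in luminal cells. Genes of inflammation and NF-kB signalling stood higher in the cells given EFNA3, with a mean log2 difference of 0.27 ± 0.07 over 29 tested genes (SD of the 3 EFNA3 libraries). The acute-phase genes Saa3 and Saa1 were higher by 0.80 (SE 0.17) and 0.62 (SE 0.15), and the neutrophil chemokine Cxcl5 by 0.45 (SE 0.10). Interferon-stimulated genes averaged 0.27 higher and MHC class I genes 0.13 higher. Ribosomal protein and oxidative phosphorylation genes averaged 0.34 and 0.24 higher, while fatty acid and triglyceride synthesis genes averaged -0.10. No single gene passed the limma test over all 16394 genes, where the smallest adjusted p was 0.55.

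In the inflammatory list, 25 of 29 genes were higher and 11 had no overlap between groups. Of all tested genes 16.0% had no overlap, where chance gives 10%. The list rose by camera (adjusted p = 1.35e-07, or 0.66 with an estimated correlation). At an estimated correlation the unadjusted camera p was 0.027 for this list, the only 1 of 43 under 0.05. It was 0.15 for ribosomal and 0.19 for oxidative phosphorylation genes, which share the adjusted 0.66. The mean of the inflammatory list lay above all controls in 3 of 3 EFNA3 libraries. When limma p-values were adjusted over the list alone, 5 genes passed, against 0 over all genes tested: Saa1, Saa2, Saa3, Cxcl5 and Nfkbia, the NF-kB inhibitor that NF-kB itself induces. Nfkbia went from 11.09 ± 0.06 to 11.40 ± 0.15 (log2, SD, n = 3), and Saa2 from 9.95 ± 0.15 to 10.55 ± 0.35. The count over the list alone was 0 without control replicate 1, 0 without control replicate 3 and 1, Saa3, without control replicate 2. With a replicate block it was 4: Nfkbia was lost with the numbers of the titles, and Nfkbia and Cxcl5 with those of the descriptions, where Cxcl2 passed. The count was 5 without EFNA3 replicate 1, where camera gave adjusted p = 0.27 with an estimated correlation. The tumour necrosis factor gene Tnf differed by 0.11 (SE 0.09) and the prostaglandin synthase gene Ptgs2 by -0.04 (SE 0.13); these were picked after their values were seen, as members that moved little.

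Among 30 tested interferon-stimulated genes, 19 were higher and 10 had no overlap between groups, against 16.0% of all tested genes. The chemokine gene Cxcl10 was 3.64-fold higher, going from 4.15 ± 0.37 to 6.01 ± 0.71 (log2, SD, n = 3), and the antiviral gene Rsad2 was 2.33-fold higher. Ifit1 differed by 1.04 (SE 0.32) and Rtp4 by 0.32 (SE 0.11). The list rose by camera (adjusted p = 0.00237; adjusted p = 0.66 with an estimated correlation), and 2 genes, Cxcl10 and Rsad2, passed limma adjusted over the list alone, against 0 over all genes tested. Without control replicate 3 the call was lost (adjusted p = 0.15) and 0 genes passed over the list alone. The count over the list alone was also 0 without control replicate 2 and 1, Cxcl10, without control replicate 1, EFNA3 replicate 1 or EFNA3 replicate 3. EFNA3 replicate 1 carried the highest list mean, 0.45, against 0.22 and 0.14 in the others, and the mean difference without it was 0.18. The groups overlapped, since control replicate 2 lay at 0.1453 and EFNA3 replicate 3 at 0.1450; the 95% interval of the difference, from the spread of list means between libraries, ran from -0.09 to 0.63.

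MHC class I and antigen presentation genes, 13 tested, rose by camera (adjusted p = 0.00724; adjusted p = 0.66 with an estimated correlation), with 11 higher. Beta-2 microglobulin, B2m, was higher by 0.28 (SE 0.08) and the immunoproteasome gene Psmb10 by 0.32 (SE 0.12). The peptide-loading genes Tapbp and Tap2 were higher by 0.23 (SE 0.11) and 0.23 (SE 0.11). The call was lost with a replicate block by the numbers of the descriptions (adjusted p = 0.245). No member passed limma over all genes tested or adjusted over the list alone, while 2 stood at an unadjusted p under 0.05. Without EFNA3 replicate 1, and without EFNA3 replicate 3, B2m passed over the list alone. The unadjusted count was 1 without control replicate 1, control replicate 2 or EFNA3 replicate 1, and 6 without control replicate 3 or EFNA3 replicate 3.

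**Figure D1:**
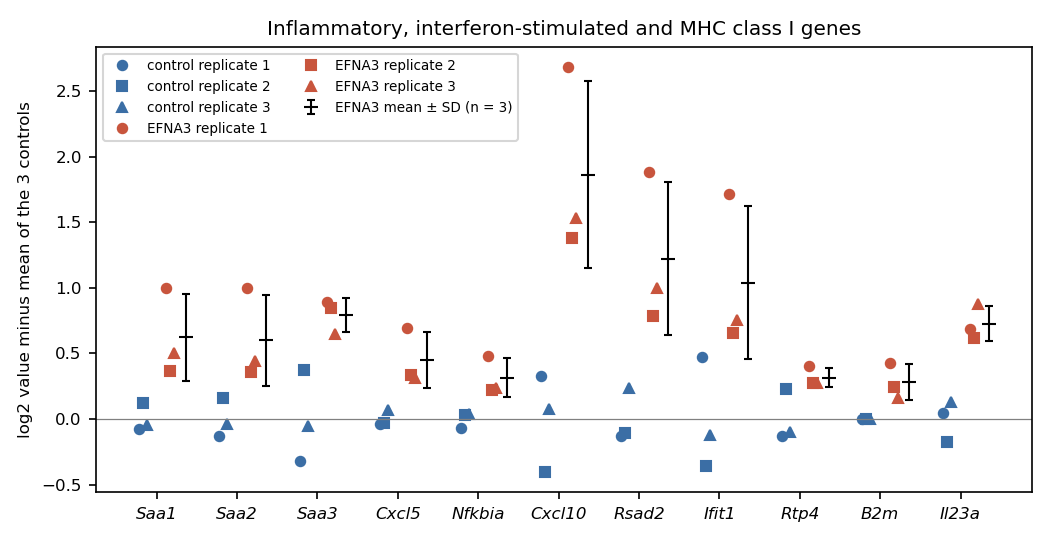
Log2 values of 10 inflammatory, interferon-stimulated and MHC class I genes and of Il23a in each library, given as the difference from the mean of the 3 controls; black bars give the EFNA3 mean and SD (n = 3). Cxcl10 differs most, by 1.86. The point for EFNA3 replicate 1 lies above the other EFNA3 libraries in Saa1, Saa2, Saa3, Cxcl5, Cxcl10, Rsad2, Ifit1, Rtp4 and B2m, but not in Il23a.

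All 51 ribosomal protein genes and all 32 nuclear-encoded oxidative phosphorylation genes tested had higher group means with EFNA3. Rplp2 was higher by 0.61 (SE 0.17), Rps20 by 0.44 (SE 0.13), the complex I gene Ndufa1 by 0.42 (SE 0.13) and the cytochrome oxidase gene Cox6c by 0.39 (SE 0.14). Both lists rose by camera, the ribosomal list at adjusted p = 3.05e-15 and the oxidative phosphorylation list at 3.57e-10, and each had adjusted p = 0.66 with an estimated correlation. No member passed limma over all genes tested or adjusted over the list alone; 16 ribosomal and 12 oxidative phosphorylation genes stood at an unadjusted p under 0.05. Single libraries moved these counts: over the list alone 26 ribosomal genes passed without EFNA3 replicate 2 and 2 without EFNA3 replicate 1, and the unadjusted ribosomal count was 32 without EFNA3 replicate 2 and 5 without control replicate 3. With a replicate block by the numbers of the titles 8 ribosomal genes passed over the list alone, and with that by the descriptions 19 ribosomal genes and Atp5h. The unadjusted oxidative phosphorylation count was 7, 4 and 3 without control replicates 1, 2 and 3. The ribosomal mean was 0.64, 0.08 and 0.29 in EFNA3 replicates 1, 2 and 3 and 0.12, 0.05 and -0.18 in the controls, so EFNA3 replicate 2 lay below control replicate 1. The oxidative phosphorylation mean was 0.51, 0.11 and 0.11, above all controls. Without EFNA3 replicate 1 the mean differences were 0.19 and 0.11, and both lists were still called at the preset correlation, but not at an estimated one (adjusted p = 0.43 and 0.27).

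These lists hold short transcripts, with medians of 1109 and 1298 nt, and EFNA3 replicate 1 departed from the other libraries by transcript length. Its deviation from the mean of 6 libraries was 0.33 in the shortest eighth of genes, up to 1504 nt, and -0.34 in the longest, from 6402 nt. Across genes, which are not independent replicates, the Spearman correlation of that deviation with length was -0.69; the other libraries lay between 0.05 and 0.59. Across genes, the log2 difference between groups had a Spearman correlation of -0.64 with length, and -0.41 without that library.

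**Figure D2:**
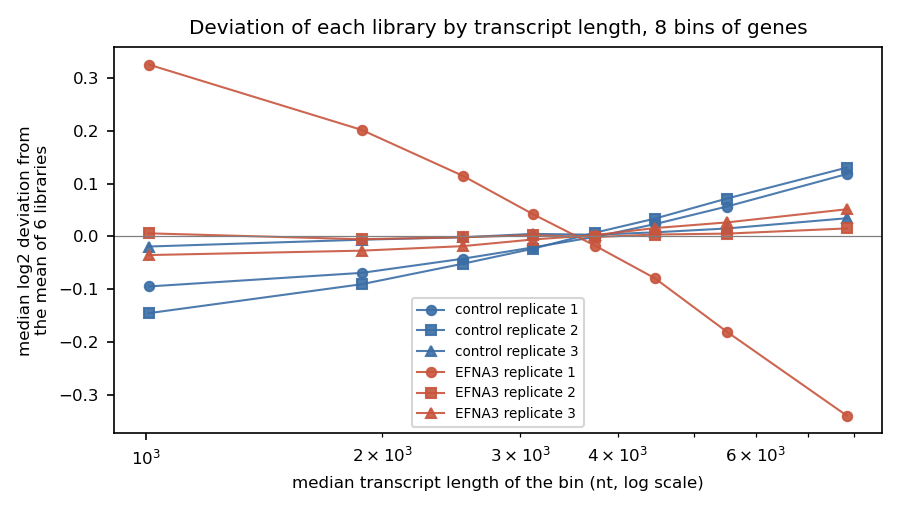
Median log2 deviation of each library from the mean of 6 libraries, in 8 bins of genes by transcript length (nt, log axis). EFNA3 replicate 1 falls from 0.33 in the shortest bin to -0.34 in the longest, while the other libraries stay between -0.15 and 0.13.

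Genes of fatty acid and triglyceride synthesis stood lower with EFNA3, while cholesterol biosynthesis genes, 13 higher and 12 lower, averaged 0.02 (camera adjusted p = 0.99, direction down). In the fatty acid and triglyceride synthesis list, 16 of 21 genes were lower, and the list mean lay below all controls in 3 of 3 EFNA3 libraries. The margin was small, with EFNA3 replicate 2 at -0.028 and control replicate 2 at -0.020. The interval of the difference, computed as for interferon-stimulated genes, ran from -0.24 to 0.03 and so reached both sides of no difference. The elongase gene Elovl6 differed by -0.29 (SE 0.10), the lipin gene Lpin1 by -0.34 (SE 0.13), the ATP-citrate lyase gene Acly by -0.17 (SE 0.07) and the fatty acid synthase gene Fasn by -0.34 (SE 0.14). The list fell by camera (adjusted p = 0.0147; adjusted p = 0.66 with an estimated correlation), with 0 genes past limma over all genes tested or adjusted over the list alone and 4 at an unadjusted p under 0.05. That unadjusted count was 1 without control replicate 1, 0 without control replicate 2 and 1 without control replicate 3. The call was lost without control replicate 1 (mean -0.085, adjusted p = 0.081) and without EFNA3 replicate 3 (mean -0.106, adjusted p = 0.11). The mean difference without EFNA3 replicate 1 was -0.06, with adjusted p = 0.43 at an estimated correlation. With the length and GC correction the mean moved from -0.104 to -0.059 (adjusted p = 0.0162), and 8.64% of random lists matched on length, GC share and level had a median as low, or 0.41% without EFNA3 replicate 1.

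Integrin and focal adhesion genes averaged -0.13 over 26 tested, with 20 lower, among them the tensin gene Tns1 at -0.46 (SE 0.19) and Itga5 at -0.23 (SE 0.11). The list fell by camera (adjusted p = 0.00924; adjusted p = 0.82 with an estimated correlation). It rested on EFNA3 replicate 1, whose list mean was -0.33 against 0.01 and -0.06 in the others: without that library the mean was -0.02 and adjusted p = 0.27, and without EFNA3 replicate 2 the mean was -0.19. These are long transcripts, with a median of 4834 nt, and with the length and GC correction adjusted p was 0.36. General luminal keratins and epithelial identity genes averaged 0.11 higher over 21 tested, among them Krt7 at 0.22 (SE 0.09) and Krt19 at 0.21 (SE 0.09). That list rose by camera (adjusted p = 0.00931; adjusted p = 0.74 with an estimated correlation); without control replicate 2 adjusted p was 0.059, with the length and GC correction it was 0.056, with a replicate block by the numbers of the descriptions it was 0.245, and the mean without EFNA3 replicate 1 was 0.06. In both lists 0 genes passed limma over all genes tested or adjusted over the list alone; 1 and 3 stood at an unadjusted p under 0.05. That integrin count was 0 without control replicate 3 or EFNA3 replicate 1, 2 without EFNA3 replicate 3 and 5 without EFNA3 replicate 2. The general luminal count was 0 without control replicate 1 or control replicate 2, 1 without EFNA3 replicate 2 and 7 without EFNA3 replicate 3.

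Apart from the general luminal list, lists for mammary cell types were not called by camera with all 6 libraries as deposited and equal weights. Luminal progenitor markers averaged 0.05 (adjusted p = 0.17), hormone-sensing markers -0.00 (adjusted p = 0.90; median 0.01) and basal markers -0.08 (adjusted p = 0.29). Without EFNA3 replicate 1 the luminal progenitor mean was 0.004 and the basal mean -0.02; without EFNA3 replicate 2 these were 0.09 and -0.12, and without control replicate 2 the luminal progenitor mean was 0.03. Fibroblast markers averaged 0.22 (adjusted p = 0.65) and endothelial and pericyte markers 0.03 (adjusted p = 0.91; median -0.00). The fibroblast mean was 0.11 without EFNA3 replicate 2 and 0.33 without EFNA3 replicate 3. The endothelial mean fell below 0 without EFNA3 replicate 1 (-0.05), control replicate 1 or control replicate 2 (-0.02 each), and was 0.01 without EFNA3 replicate 2 and 0.12 without control replicate 3 or EFNA3 replicate 3. For milk genes the mean was 0.06, the median -0.01 and camera's direction down (adjusted p = 0.90), so these differ in sign. The milk mean was -0.03 without EFNA3 replicate 1, 0.01 without control replicate 2 and 0.11 without control replicate 3 or EFNA3 replicate 3. Without EFNA3 replicate 1 the milk list was called lower (adjusted p = 0.030), but not at an estimated correlation (adjusted p = 0.43). Of the immune marker list only 3 genes, Csf1r, Cd68 and Cd74, were tested, at mean differences of 0.41 (SE 0.30), -0.13 (SE 0.15) and -0.01 (SE 0.48). Adipocyte markers averaged -0.21 over 7 genes (median -0.11, adjusted p = 0.14) and lay below all controls in 3 of 3 EFNA3 libraries. The mean leaned on Plin1 at -0.87 (SE 0.67), a low gene that ran from 1.28 to 3.67 in EFNA3 libraries. The list mean was -0.16 with a pseudocount of 5 and -0.09 with no filter on low values. It was -0.26 with library weights and -0.26 with the length and GC correction. A filter 5 times stricter left 4 genes, too few to test. Without EFNA3 replicate 1 the adipocyte list was called lower (adjusted p = 0.00111). At an estimated correlation it was not (adjusted p = 0.43, or 0.66 with all libraries). It was also called lower with all 6 libraries by library weights (adjusted p = 0.00356) and by the length and GC correction (adjusted p = 0.0162). Named members included Krt15 at 0.21 (SE 0.09), the prolactin receptor gene Prlr at -0.31 (SE 0.12), Mylk at -0.45 (SE 0.19), Fbln1 at -0.31 (SE 0.10) and Lpl at -0.35 (SE 0.13). Without EFNA3 replicate 1, Prlr stood at -0.16 and Mylk at -0.21. Of hormone-sensing genes, 1 higher and 3 lower had an unadjusted limma p under 0.05. The higher gene, Cited1, differed by 0.63 (SE 0.23). With all 6 libraries and equal weights no member of the cell type lists passed limma over all genes tested or adjusted over the list alone. Over the list alone, the adipocyte genes Lpl and Fabp4 passed without EFNA3 replicate 1, and these and Pparg with library weights.

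**Figure D3:**
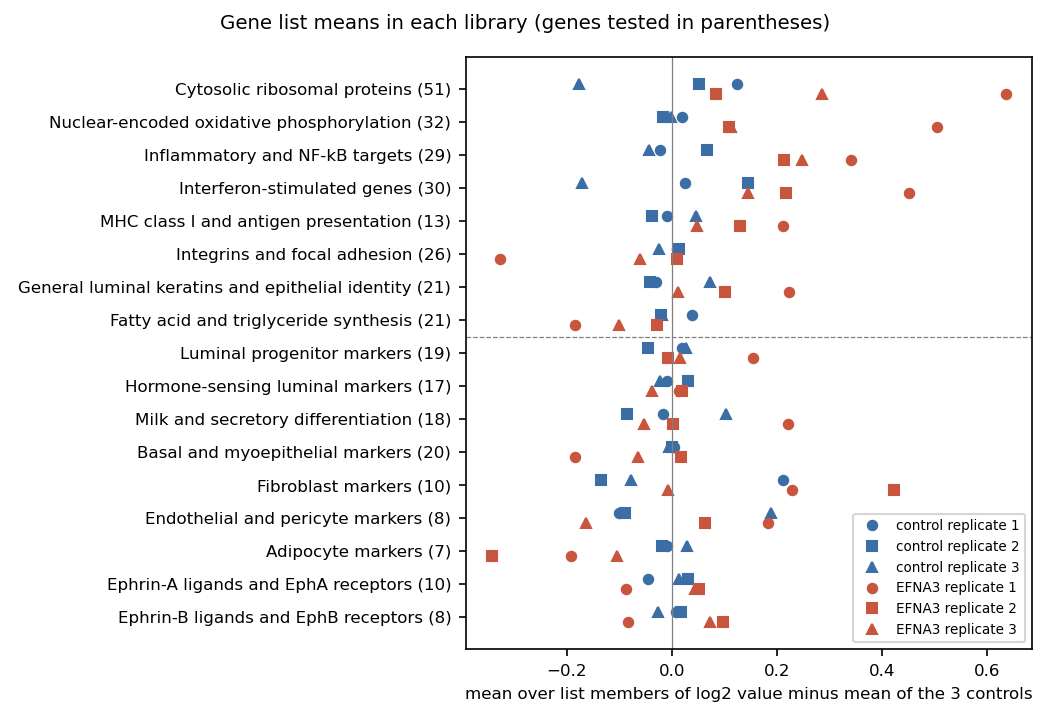
Mean over list members of the log2 value minus the mean of the 3 controls, for each library; lists above the dashed line were called by camera with the preset correlation. The inflammatory list has all 3 EFNA3 libraries above all controls, from 0.21 to 0.34, while for integrins EFNA3 replicate 1 lies at -0.33 and the others at 0.01 and -0.06.

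None of the 18 tested ephrin and Eph genes passed limma, over all genes tested or adjusted over the list alone, and 1 stood at an unadjusted p under 0.05; that count was 0 without any 1 of the controls or without EFNA3 replicate 1. Efna3 itself ran from 8.80 to 9.19 in the 3 controls and from 8.97 to 9.11 in the 3 EFNA3 libraries (log2), a difference of 0.05 (SE 0.11); its transcript does not check a treatment with protein. Efna4 was higher by 0.18 (SE 0.08) and Efna1 by 0.18 (SE 0.09). Ephb4 and Ephb6 were the most abundant receptors, at 12.4 and 12.2, and differed by -0.00 (SE 0.07) and -0.02 (SE 0.07). Epha2, a receptor of A-type ephrins, differed by -0.01 (SE 0.07), Epha4 by -0.13 (SE 0.13) and Epha7 by -0.22 (SE 0.13). Differences of the remaining members, Efna2, Efna5, Epha1, Epha3, Ephb1, Ephb2, Ephb3, Efnb1, Efnb2 and Efnb3, lay between -0.11 and 0.21. The ephrin-A list averaged 0.00 (camera adjusted p = 0.96, direction up; median -0.01) and the ephrin-B list 0.03 (camera adjusted p = 0.65). Without EFNA3 replicate 1 these means were 0.05 and 0.08 (adjusted p = 0.27 and 0.093). With the length and GC correction as well, the ephrin-B list was called higher (mean 0.11, adjusted p = 0.0158). At an estimated correlation its camera adjusted p was 0.97 with all libraries and 0.53 without EFNA3 replicate 1, both as deposited. Without EFNA3 replicate 2 the means of the ephrin-A and ephrin-B lists were below 0, at -0.02 and -0.01.

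Within the rule's limits on mean level, overlap and predicted genes, 10 genes higher with EFNA3 were named by smallest unadjusted p. They were Wif1, Saa3, Id3, Comtd1, Rpl9-ps7, Il23a, Cxcl5, Saa1, Ndufs6 and C1qtnf3, and none passed (limma adjusted p = 0.55). The Wnt inhibitor gene Wif1 went from 8.84 ± 0.09 to 9.30 ± 0.09 (log2, SD, n = 3). The BMP target gene Id3 was higher by 0.49 (SE 0.11), the cytokine subunit gene Il23a by 0.73 (SE 0.17) and C1qtnf3 by 1.12 (SE 0.27). The 10 lower genes, also at adjusted p = 0.55, were Cyp2b19, Far2, Arhgef6, Tgfbr3, Cd36, Sox6, Soat1, Fa2h, Mgll and Hsd3b6. Of these, the fatty acyl reductase gene Far2 differed by -0.43 (SE 0.10), the fatty acid transporter gene Cd36 by -0.51 (SE 0.13), the cholesterol acyltransferase gene Soat1 by -0.28 (SE 0.07), the fatty acid hydroxylase gene Fa2h by -0.34 (SE 0.09) and the monoglyceride lipase gene Mgll by -0.30 (SE 0.08). Cyp2b19 differed by -0.73 (SE 0.15).

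Over all genes, limma called 0 at an adjusted p under 0.05 and 1104 at an unadjusted p under 0.05, of which 635 were higher and 469 lower, where 819.7 would arise by chance. That unadjusted count was 568 without control replicate 1, 512 without control replicate 2, 1801 without EFNA3 replicate 2 and 2478 without EFNA3 replicate 3. Groups did not overlap for 1398 higher and 1221 lower genes, 16.0% of those tested, where chance gives 10%. The median SE of a log2 difference was 0.12. Camera with the preset correlation called 8 of 43 lists, 6 higher and 2 lower, and 15 without EFNA3 replicate 1; 0 were called with an estimated correlation, with all libraries or without that one, and fry called 0, with a smallest adjusted p of 0.22. Lists for S phase (mean 0.03, adjusted p = 0.64), mitosis (0.00, median -0.01, direction down, adjusted p = 0.96) and MAPK feedback genes (0.00, median -0.00, adjusted p = 0.90) were not called by camera.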

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

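The length and GC correction, alone or with EFNA3 replicate 1 left out, was chosen after seeing the data. The count of genes past the limma threshold was 0 in every alternative run but 1, including each left-out library (0 to 0), and 0 of 18 ephrin and Eph genes passed in any (0 to 0). The exception was the replicate block by the numbers of the descriptions, with 71 genes, 53 higher and 18 lower. That fit leaves 1 residual degree of freedom and an infinite prior, and its difference came only from replicates 1 and 3 of each group. Of the 71, 24 had symbols of ribosomal proteins or their pseudogenes, 20 were predicted genes, 3 belonged to the inflammatory list (Saa1, Saa2, Saa3) and 1 to the interferon list (Cxcl10). It called 6 lists, without those for MHC class I and general luminal genes (adjusted p = 0.245 each). The replicate block by the numbers of the titles gave 0 genes and 9 lists. Libraries with the same title number had deviations that correlated at -0.16, 0.07 and -0.58 across genes, so the numbers share no visible pairing, and not every library correlated best with its own number. The count of lists was 8, and ranged from 7 to 15 when single libraries were left out, the 15 being without EFNA3 replicate 1. It was 17 with the length and GC correction and EFNA3 replicate 1 left out, and 0 with an estimated correlation; the cause was not tested. The integrin list reversed to 0.00615 (adjusted p = 0.66) with that correction and that library left out. Of the interferon-stimulated genes, 0 passed over the list alone with a filter 5 times stricter, which tests fewer of them. Of the 20 genes named by smallest p, 0 changed sign in any alternative. This largely follows from their choice, since only genes with no overlap between groups were eligible. The other named genes, not chosen in that way, changed sign 55 times, at values not past the threshold. Quantile normalization was not run, since the values already share 1 distribution, and count models were not run, since whole reads could not be recovered from log2 values. Without counts, what depth limits cannot be stated.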

Other observations

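The tests in this part were chosen after the result was seen, except the counts over other splits of the libraries; the rule for RNA of another cell type was also changed after its first value was seen.

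Some lists were not called with all libraries as deposited and were called without EFNA3 replicate 1. Among them were lists of stress and RNA quality: mitochondrially encoded genes (adjusted p = 0.00299), heat shock and dissociation stress (0.041) and p53 targets (0.047), each higher. With the length and GC correction the mitochondrial list turned to -0.04 (adjusted p = 0.96), while with EFNA3 replicate 1 also left out it was 0.03 (0.26). Targets of TGF-beta and BMP averaged 0.09 over 19 genes, above all controls in 3 of 3 EFNA3 libraries; camera gave adjusted p = 0.14 with all libraries, 0.00111 without EFNA3 replicate 1 and 0.00638 with the correction, and adjusted p = 0.66 with an estimated correlation. Id3 was its only member to pass limma adjusted over the list alone, against 0 over all genes tested; it did not pass without control replicate 1, control replicate 2 or EFNA3 replicate 2, or with either replicate block. The Wnt list was not called with all libraries (mean 0.08, median -0.01, camera adjusted p = 0.89) or without EFNA3 replicate 1 (0.064). It was called with the length and GC correction and that library left out (mean 0.14, adjusted p = 0.00595). At an estimated correlation its camera adjusted p was 0.99 with all libraries and 0.49 without EFNA3 replicate 1. In the main fit Wif1 was its only member to pass limma adjusted over the list alone. With the correction and EFNA3 replicate 1 left out, Nkd2 passed beside it. Wif1 did not pass without control replicate 1, control replicate 3 or EFNA3 replicate 2, or with the block by the numbers of the descriptions. Keratinization genes averaged 0.14, at 0.15, 0.14 and 0.12 in the EFNA3 libraries. Control replicates 1, 2 and 3 lay at 0.10, -0.17 and 0.07, so the difference came mainly from control replicate 2. Camera gave keratinization genes adjusted p = 0.12, 0.0107 without EFNA3 replicate 1 and 0.36 with the length and GC correction. Genes of the FoxO and starvation response averaged -0.08, below all controls in 3 of 3 libraries, with camera adjusted p = 0.12, 0.0356 without EFNA3 replicate 1 and 0.99 with the correction. Both lists had adjusted p = 0.66 with an estimated correlation. At an estimated correlation none was called without EFNA3 replicate 1 either: adjusted p was 0.43 for TGF-beta and BMP, FoxO, mitochondrially encoded and heat shock genes, and 0.49 for keratinization and p53 targets.

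The inflammatory list was higher in every EFNA3 library. Of 10000 random lists matched on length, GC share and level, 0% had a median as large. This cannot exclude a trend with transcript length and GC share as the whole cause. The matched genes were drawn independently, which ignores correlation within the list, and the longest annotated transcript may not be the one expressed. EFNA3 replicate 1 as the only source is argued against: without it the list means per library still differed by 0.23. The 95% interval was 0.09 to 0.37, from the spread between libraries taken as normal. Variation between libraries shared by these genes stays open. With an estimated correlation of 0.093 the camera adjusted p was 0.66, though the list means did not overlap between groups. The lost call alone cannot show shared variation, since p also rose where the estimated correlation was not positive. For adipocyte markers, at an estimated correlation of -0.024, the unadjusted camera p went from 0.043 to 0.106. Another component of the protein preparation may also account for the rise of the inflammatory list, and cannot be told apart from EFNA3 because 0 libraries were given another protein. A response to EFNA3 is a hypothesis that stays untested against these.

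The ribosomal and oxidative phosphorylation lists were higher in all their members. Length and GC share went with a large part of the change: matched lists had medians of 0.151 and 0.146, against 0.286 and 0.253. For either list 0% of matched random lists had a median as large. This cannot exclude length and GC share as the whole cause. Matched genes were drawn independently, while list members had estimated correlations of 0.65 and 0.76. Length was that of the longest annotated transcript, 3706 nt for Rps20 and 3038 nt for Cox6c, which may not be the one expressed. With the correction the mean differences fell from 0.34 to 0.22 and from 0.24 to 0.14, and to 0.14 and 0.066 with EFNA3 replicate 1 also left out. EFNA3 replicate 1 as the only source is argued against for oxidative phosphorylation, where without it the list means per library differed by 0.11 (95% interval 0.07 to 0.15), or with the correction by 0.066 (0.00065 to 0.13). For ribosomal proteins it stays open, at 0.19 (-0.26 to 0.63). With all libraries as deposited the 95% intervals reached both sides of no difference. They ran from -0.12 to 0.61 for oxidative phosphorylation and from -0.18 to 0.85 for ribosomal proteins. For the other called lists the share of matched lists with a median as extreme was 0.09% for interferon-stimulated genes, 0.08% for MHC class I, 0.52% for integrins, 8.64% for fatty acid synthesis and 11.85% for general luminal genes. Without EFNA3 replicate 1 the last 3 turned over, to 23.32%, 0.41% and 2.39%. Shared variation between libraries may account for the ribosomal list, where the estimated correlation between genes was 0.65 and the groups overlapped. The camera adjusted p of 0.66 there cannot show it alone, for the reason given for the inflammatory list. For the oxidative phosphorylation list shared variation cannot be told apart from an effect of EFNA3. Its estimated correlation was 0.76 and its camera adjusted p 0.66, with no overlap of list means. A response to EFNA3 was not excluded.

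EFNA3 replicate 1 lay 2.09 times as far from the other EFNA3 libraries as those from each other, as a root mean square log2 difference. After the length and GC correction the ratio was 1.69. This cannot exclude that trend as the whole cause, since the correction used the longest annotated transcript of each gene. A control under an EFNA3 label is argued against as the whole cause of its distance. EFNA3 replicate 1 lay 0.339 to 0.403 from the controls, which lay 0.155 to 0.177 from each other. After the correction these ranges were 0.266 to 0.301 and 0.153 to 0.162. Whether its label is right stays open. Its mean distance to the controls was larger than to the other EFNA3 libraries by 0.0587, but this distance placed 2 of the other 5 libraries closer to their own group. RNA from another cell type may contribute and stays open: the largest excess of a marker list over both other EFNA3 libraries was 0.19 (SE 0.11), for endothelial and pericyte markers, whose most abundant gene, Notch3, stood at 12.2 in controls. Immune markers were not in that comparison, as few passed the filter; the myeloid gene Lyz2, singled out after its values were seen, stood at 5.87 in EFNA3 replicate 1 and between 1.37 and 3.16 in the other libraries, while Cd68 stood at 7.14, within their range. The cells had been sorted as luminal by flow cytometry. Depth, RNA integrity and batch were not analysed here.

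Some of the 10 lower genes, none past the limma threshold, act on lipids, which prompted the hypothesis that sebaceous-type lipid genes may be lower as a class. Of 13 other tested sebaceous genes, 8 were lower, with a mean of -0.07. Camera gave an unadjusted p of 0.185 for this list, so the question stays open.

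The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest other split 0, so all 10 gave as many; at an unadjusted p under 0.05 the real split gave 1104 and the highest other 2008. For lists the real split gave 8 and the highest other 9, with 4 of 10 splits giving as many. Genes past limma adjusted over their list alone numbered 9 in the real split and 17 in the highest other. The camera p of the real split and the smallest of the others were 9.44e-09 and 3.00e-05 for the inflammatory list (1 split as small, the real one), 1.66e-11 and 6.94e-09 for oxidative phosphorylation (1 split), and 7.09e-17 and 9.37e-25 for ribosomal proteins (3 splits). They were 0.000220 and 2.53e-07 for interferon-stimulated genes (3 splits), 0.000841 and 0.000790 for MHC class I (2 splits), and 0.00274 and 0.000880 for fatty acid synthesis (2 splits). For general luminal genes they were 0.00151 and 1.78e-05 (2 splits), and for integrins 0.00129 and 6.49e-06 (7 splits).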
